A study of Drosophila melanogaster with 3 samples.

How the data were processed

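Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos aged 4 to 16 hours, from a transgenic line in which GFP is fused to the C terminus of unpg (unplugged, a homeodomain transcription factor). The labels disagree on the antibody: the sample descriptions say that the precipitation used an anti-GFP antibody, which is followed here, while the antibody field names unpg. Per the labels, chromatin was sonicated to 200 to 800 bp. The labels give 3 biological replicates, numbered 3, 4 and 5, in 1 group, so no comparison between groups could be made. Per the labels a control library was shared by the replicates; its reads were not analysed here.

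The deposited files were 5 peak lists on the dm6 assembly. Per the file descriptions deposited with them, the authors called peaks on each replicate's alignments and on the alignments of all 3 replicates together, each against 1 shared control, and derived a further list by the irreproducible discovery rate (IDR) from these. The aligner, the peak caller, the versions and the IDR threshold are not given in the sources used here. Each replicate list and the pooled list held exactly 30000 peaks, so these lists end at a fixed number. The IDR list held 7176 peaks and was the same set as the 7176 pooled peaks of highest signal value. Of the other 22824 pooled peaks, 721 shared bases with an IDR peak, and the remaining 22103 are called pooled peaks outside the IDR set. Because the IDR list was derived from the replicate lists, the share of IDR peaks found in them is not an independent check.

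The deposited signal score of each peak is the authors' own value, its scale is not stated, and it was used only to rank or describe peaks within 1 list. The deposited -log10 q-value of each peak reached the same ceiling of 4.37 in all 7176 IDR peaks and was therefore not used for ranking. Of the 22103 pooled peaks outside the IDR set, 4297 were at this ceiling, and the value went down to 0.359 in the pooled list. Lists of a fixed length thus let in calls with little support, which limits the outside peaks as a background. The lists carry no read counts, so the sequencing depth behind each peak is unknown. Binomial intervals below are 95% Wilson intervals over peaks, windows or genes and cover counting error only.

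Lists were read with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. Arm sequences came from the Release 6 reference genome and genes from Ensembl release 115 on the same assembly. All peaks lay on the 6 arms 2L, 2R, 3L, 3R, 4 and X, within the reference lengths. Coordinates are 1-based.

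In the overlap of replicates, the 7176 strongest peaks of each replicate were compared, 1 bp of overlap counting as shared, and set beside 100 random placements on the same arms. Each IDR summit was assigned in this order to a promoter (within 500 bp of a transcription start site, TSS, of a protein-coding gene), 5' UTR, CDS, 3' UTR, intron, other gene or intergenic DNA, and compared with 1000 random placements. The smallest two-sided permutation p these allow is 0.002. Arms were tested with exact binomial tests against their share of length. A summit was assigned to the gene of the nearest TSS within 20 kb. For each of 19 gene lists, the number of members with a summit was compared with 10000 random lists matched on the decile of catchment length, the length of DNA for which a gene's TSS is the nearest. The smallest two-sided permutation p these allow is 0.0002. For 14 motifs, the window within 50 bp of the summit was compared with a window of the same size centred 300 bp to the right, by the exact McNemar test. All 6-mers found in 1% or more of the flank windows were ranked by the ratio of summit to flank share. Fisher's exact test compared the 1794 strongest with the 1794 weakest IDR peaks, and promoter with other summits. All tests were two-sided, with Benjamini-Hochberg adjustment within each family and a threshold of 0.05. Peaks and genes are not independent replicates, so these tests describe the peak lists; values per replicate (mean ± SD, n = 3) come from the 7176 strongest peaks of each replicate list.

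The groups, tests, gene lists, motifs, the rule for named genes and most alternatives were set before the data were examined. The rule names unpg, the nearest gene of the 12 strongest IDR peaks, the 10 genes with the most assigned summits, and from each list up to 3 members with the most summits and members with none. Of the list symbols, 6 were not in the annotation and were left out (six3, h, duf, hnt, nos and svb). In the reference gene table all 6 are older names of annotated genes (Optix, hry, kirre, peb, nanos and ovo), of which Optix was already in its list, so 5 lists lack 1 intended member each. The alternatives varied the overlap rule, the peak set, the promoter and motif windows, the background, the assignment to genes, the flank and the base composition control, and left out each replicate in turn. Matching on GC content, leaving out promoter summits and resolving the older symbols were added after the data had been seen. No 2 replicate lists shared more than 3 peaks with identical start and end, so none was a copy of another.

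The overlap of replicates, the annotation, arm, gene list and motif tests and the 6-mer ranking were tested on simulated data. The share of IDR peaks found in the replicates, the signal correlation, the comparisons of strong with weak peaks and of promoter with other summits, the GC-matched comparisons and the tests on tRNA genes and divergent gene pairs were not. For strong and weak peaks only the arithmetic of the difference was checked, on fixed counts. Of 7176 simulated peaks, 60.0% planted as shared were found at 61.0%, with 2.55% overlapping by chance. A list of 92 genes with planted 3-fold occupancy was called in 20 of 20 simulations, and 0 of 380 list tests without effect were called. No effect was planted in a smaller list, so how often the smaller lists would be called is unknown. A planted TAATTA share of 15.9% over 7176 windows was found at 15.9%, and 0 of 14 motifs without effect and 1 of 120 arm tests without effect were called. The simulated motif windows lay at random positions, without the GC difference of the data (31.8% at IDR summits against 43.9% in flanks). The 0 of 14 therefore does not cover motif calls that arise from base composition.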

Results

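GFP-tagged unpg was profiled by ChIP-seq in whole embryos of 4 to 16 hours, in 3 biological replicates of 1 group. An anti-GFP antibody was used according to the sample descriptions. No precipitation from untagged embryos was used here, so whether each peak depends on the tagged protein was not tested. The unpg gene encodes a homeodomain transcription factor known from the formation of the cerebral tracheal branch and from the embryonic brain. The data were peak lists on dm6, with 30000 peaks in each of replicates 3, 4 and 5, 30000 peaks in the pooled list, and 7176 peaks in the IDR list, the authors' set of peaks reproducible between replicates. The lists carry no read counts, so the depth of each replicate is unknown.

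The first comparison asked how far the replicates held the same regions. Of the 7176 strongest peaks of 1 replicate, 79.6% ± 1.15 (SD over 3 replicate pairs) overlapped one of the 7176 strongest of another, against 2.95% ± 0.211 (SD over 100 placements) at random positions. The strongest IDR peaks were strong in each replicate: all 12 of the top IDR peaks were among the 50 strongest peaks of replicates 3, 4 and 5, and 9, 11 and 11 of them were among the 12 strongest. The share of IDR peaks with a top peak was 88.1% in replicate 3 (95% Wilson interval 87.4 to 88.9), 87.0% in replicate 4 (86.2 to 87.8) and 84.4% in replicate 5 (83.6 to 85.3), and 70.4% (69.3 to 71.5) had one in all 3. Across IDR peaks, which are not independent replicates, Spearman's rho of the signal values was 0.843 between replicates 3 and 4, 0.827 between 3 and 5 and 0.847 between 4 and 5. With 50% reciprocal overlap required, the share of IDR peaks found in all 3 replicates was 48.7%.

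The tagged gene itself was the next locus. unpg (FBgn0015561, 2R 9195205 to 9199870, plus strand) carried 2 IDR peaks, and 2 peaks in the 7176 strongest of each replicate (mean 2, SD 0, n = 3). A peak at 2R 9194977 to 9195102 lay in the promoter, its summit 131 bp upstream of the TSS, at rank 3440 of the IDR list and ranks 5782, 3078 and 2722 of replicates 3, 4 and 5. The other, at 2R 9200819 to 9201041, had its summit in intergenic DNA 5739 bp downstream of the TSS, at rank 3332 and at ranks 3261, 4061 and 3416 of the replicates. Its summit window held the homeodomain word TAATTA, as did 11.4% of all IDR summit windows, while that of the promoter peak did not. GC content was 34.7% in the intergenic and 58.4% in the promoter summit window. A stronger peak nearby, at 2R 9192051 to 9192304 and rank 2070, lay in the promoter of CG45085; this peak falls outside the naming rule and was chosen after its values were seen.

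**Figure D1:**
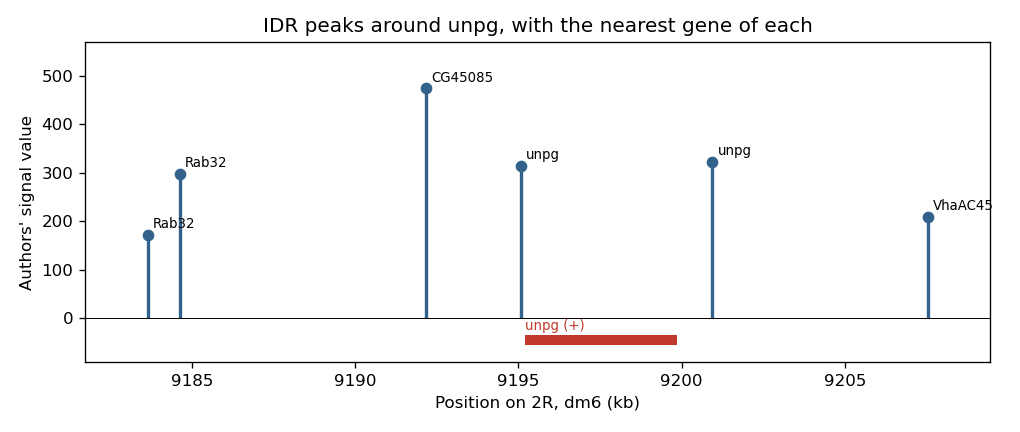
Authors' signal value (vertical axis) of IDR summits within 12 kb of unpg by position on 2R in kb (horizontal axis), each labelled with its nearest gene; the red bar is the unpg gene. The 2 summits assigned to unpg have signal values of 314 and 323, and the CG45085 summit has 474.

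The strongest peaks lay mostly at promoters. Of the 12 strongest IDR peaks 10 had promoter summits, with summit GC content from 16.8 to 33.7%. The strongest, at 3L 19590407 to 19590831, had its summit 90 bp upstream of the TSS of CG14100 and ranked 1 in each of the 3 replicates. The next were at mRpL41, which encodes a mitochondrial ribosomal protein (2R 15217570 to 15218033, 136 bp upstream), and in an intron 1024 bp from the TSS of CG11050 (2L 6612408 to 6612975). Ugalt, a UDP-galactose transporter, had a summit 39 bp upstream (X 2703673 to 2704102). Promoter summits at Art3, a protein arginine methyltransferase gene, px (plexus, known from wing vein patterning), CG5611, CG11309, CG18549, CenG1A and PNPase, the mitochondrial polynucleotide phosphorylase gene, were within 205 bp of the TSS. The remaining summit, at 2L 480885 to 481309, was intronic, 1408 bp from the TSS of cbt (cabut, a zinc finger transcription factor) and within the span of ush.

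The genes with the most summits had long catchments. ush (u-shaped, a cofactor of GATA factors) had 17 IDR summits, 14 of them in introns (12.7 ± 0.577 summits per replicate, SD, n = 3). pnt (pointed, an ETS transcription factor of the EGF receptor pathway) had 16 (15.3 ± 2.08), shn (schnurri, a zinc finger protein of Dpp signalling) 16 (17.3 ± 0.577), Tlk, a protein kinase gene, 16 (16.7 ± 2.52) and CG32264 16 (15.3 ± 1.53). bun had 14 summits, and px, RapGAP1, Ids and Eip75B, an ecdysone-induced nuclear receptor, had 13 each. Of 13945 protein-coding genes, 3750 (26.9%) had 1 or more of the 6875 assigned summits and 28 had 10 or more. Genes with 10 or more had a median catchment of 54050 bp, against 4253 bp for all genes.

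Summits were more frequent in promoters than random placements and almost never lay in coding sequence. Promoters held 36.7% of IDR summits against 11.5% of random placements (ratio 3.20; 38.6% ± 1.54 in the replicates, SD, n = 3). CDS held 11 of 7176 summits, 0.153% against 13.9% (ratio 0.0110; 0.163% ± 0.0528 in the replicates). Summits were also fewer than random in 3' UTRs, with 1.00% against 4.54%, and in intergenic DNA, with 17.6% against 27.8% (adjusted permutation p = 0.0028 for each of the 5 classes that passed, from the smallest p these placements can give). Introns held 41.6% against 39.3% at random (ratio 1.06), a direction that turned with promoters of 1000 bp (ratio 0.967), against pooled peaks outside the IDR set (0.842) and against random positions of the same GC content (0.954, added after seeing the data). The 5' UTR (ratio 0.841, adjusted permutation p = 0.303) and other genes (1.03, 0.753) did not pass. The 5' UTR was below the background with promoters of 1000 bp (ratio 0.390, adjusted permutation p = 0.0028), among the 3588 strongest peaks (0.489, 0.00559) and against pooled peaks outside the IDR set (0.621, adjusted Fisher's exact p = 0.00183). Other genes were below these outside peaks (0.746, adjusted Fisher's exact p = 0.000654). Against those outside peaks the promoter ratio was 1.90, the CDS ratio 0.114 and the 3' UTR ratio 0.493. With matched GC the CDS ratio was 0.0377 and the 3' UTR ratio 0.130. The CDS ratio, which rests on 11 summits, was 0.00521 to 0.00767 without each replicate. Of the 2636 promoter summits, 78.2% were upstream of the nearest TSS, and the median position was 114 bp upstream.

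**Figure D2:**
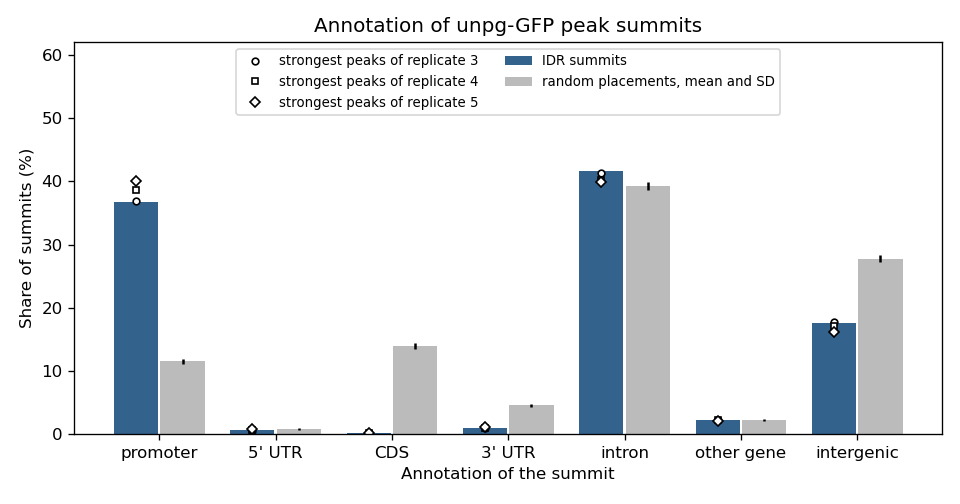
Share of summits (vertical axis, percent) by annotation class (horizontal axis) for the 7176 IDR summits, for 1000 random placements (mean, error bars SD) and for the 7176 strongest peaks of each replicate (points). Promoters hold 36.7% of IDR summits against 11.5% at random, and CDS 0.153% against 13.9%.

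By chromosome arm, IDR peaks numbered 58.7 per Mb on 2L, 57.6 on X, 54.4 on 3L, 51.2 on 3R, 49.2 on 2R and 17.1 on the small arm 4 (23 peaks). Arm 4 was below its share of length (ratio 0.318, adjusted exact binomial p = 1.36e-10; 22.3 ± 7.15 per Mb in the replicates, SD, n = 3), 2R was below (0.919, adjusted p = 0.00163) and 2L was above (1.10, adjusted p = 0.000627). X (1.07, adjusted exact binomial p = 0.00619) was above and 3R (0.955, adjusted p = 0.0385) below, and 3L did not pass (adjusted p = 0.496). Relative to pooled peaks outside the IDR set, arm 4 (ratio 0.998), 2R (0.999) and X (1.01) were no longer past the threshold and 3R turned (1.05), while 3L was below (0.8997, adjusted exact binomial p = 1.07e-05). The 3R call was also lost without any 1 replicate (adjusted exact binomial p from 0.0674 to 0.153) and the X call without replicate 3 (adjusted p = 0.0505), and the arm 4 ratio was 0.195 without replicate 5. Those settings keep fewer and mostly stronger IDR peaks, so these changes cannot be tied to 1 replicate.

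Gene lists asked whether groups of genes carried summits more often than genes with equally long catchments. Cytoplasmic ribosomal protein genes did: 71 of 92 members had a summit against 19.1 ± 3.71 (SD) in matched random lists (ratio 3.71, adjusted permutation p = 0.0019, from the smallest p these lists can give; 72 ± 2.65 members in the replicates, SD, n = 3). RpS23 had 3 summits, RpL37A and RpLP2 had 2 each, and RpL10 and RpL10Aa had none; 93.5% of the list's 77 summits were in promoters. Odorant and gustatory receptor genes, which encode chemosensory receptors, carried fewer: 7 of 119 against 32.4 ± 4.63 (ratio 0.216, adjusted permutation p = 0.0019; 7.33 ± 1.15 in the replicates). Gr93a had 5 summits, Gr93d and Gr93b had 2 each, and Gr10a and Gr10b had none. With promoter summits left out, chosen after seeing the data, 4 of the 92 ribosomal protein genes had a summit (ratio 0.546, adjusted permutation p = 0.459). The list then keeps 5 of its 77 summits, fewer than the mean of 7.32 occupied genes in matched lists. The receptor list stayed below chance in that setting (0.395, adjusted permutation p = 0.0228) and stood at 0.0315 within 1 kb of a TSS, and the ribosomal protein ratio was 2.06 with gene bodies and 2 kb.

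Tracheal development genes, a list that includes unpg, had summits at 14 of 18 members against 8.26 ± 2.09 (ratio 1.70, permutation p = 0.0116, adjusted p = 0.0735; 15.3 ± 0.577 in the replicates), which did not pass. Without replicate 3, 4 or 5, with only peaks found in both of the other replicates kept, it passed (adjusted permutation p from 0.0127 to 0.0152), as it did with promoter summits left out (ratio 1.96, adjusted permutation p = 0.0342) and without matching on catchment length (2.90, adjusted Fisher's exact p = 6.24e-05). It did not pass among the 3588 strongest peaks (adjusted permutation p = 0.111), with gene bodies and 2 kb (ratio 1.67, 0.0717), within 1 kb of a TSS (2.04, 0.0692) or with older symbols resolved (1.68, 0.0570). Its members included pnt with 16 summits, sty (sprouty, an inhibitor of receptor tyrosine kinase signalling) with 10 and rib (ribbon) with 4, while btl (breathless, the FGF receptor of the trachea) and kni had none. Axon guidance genes had 14 of 19 against 9.14 (adjusted permutation p = 0.129), with 6 summits at caps, 5 at Fas3, 4 at Sema1a and none at Con or PlexB. Dorsoventral columnar neural regulators had 7 of 8 against 3.69 (adjusted permutation p = 0.129), with 8 at sog, 4 each at brk and Dr, and none at ind. Segment polarity genes had 10 of 14 against 6.21 (adjusted permutation p = 0.156), with 6 at nkd and 5 each at ptc and wg and none at arm or gsb. Gut genes had 7 of 9 against 3.81 (adjusted permutation p = 0.156; fkh 6, caup 3, GATAe 2, byn and pnr none), and glial genes 7 of 11 against 3.89 (adjusted permutation p = 0.181; sli and loco 4 each, gcm and gcm2 none). With gene bodies and 2 kb on each side as the assignment, axon guidance (adjusted permutation p = 0.00633) and glial genes (0.0441) passed, beside cytoplasmic ribosomal protein genes. Without matching on catchment length 9 lists were above chance.

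No other list passed. Most of these lists are small, and how often a real effect in a small list would be called was not simulated. Hox genes had summits at 5 of 8 members (Antp 7, abd-A 3, Abd-B 2, Dfd and Scr none; adjusted permutation p = 0.766), brain boundary and head patterning regulators at 7 of 16 (ems 6, slp2 4, oc 3, Poxn and btd none; adjusted permutation p = 1), and other homeodomain regulators at 25 of 52 (hth 12, zfh1 6, tup 5, B-H1 and CG11085 none; adjusted permutation p = 0.612). Gap and pair-rule genes had 2 of 13 (odd 3, slp1 1, Kr and eve none; adjusted permutation p = 0.156) and neuroblast and temporal regulators 4 of 17 (grh 3, insc and esg 2 each, Kr and ac none; adjusted permutation p = 0.286). In the replicates these 2 lists had more occupied members, 4 ± 1 and 6.33 ± 1.53 (SD, n = 3). Neuronal differentiation genes had 4 of 15 (Syx1A 5, elav and fne 4 each, ChAT and Gad1 none; 0.609), muscle and mesoderm genes 9 of 17 (Mef2 7, Tm1 and rst 2 each, Mhc and Tm2 none; 0.651), and hemocyte and fat body genes 4 of 13 (ush 17, Lsp1beta 3, srp 2, Fbp1 and Hml none; 1), the last value of each being the adjusted permutation p. Germline genes had 1 of 9 (ovo 4, aub and bam none; 0.678), cuticle and late epidermis genes 2 of 13 (shd 2, Ddc 1, Cpr47Ef and Cpr66D none; 0.431), and chorion and yolk protein genes, among them Cp15 and Cp16, 0 of 16 against 3.36 (0.129), again with adjusted permutation p. The chorion and yolk protein list was below chance with gene bodies and 2 kb (ratio 0.153, adjusted permutation p = 0.0275) and without matching on catchment length (adjusted Fisher's exact p = 0.0203), and in the other settings its adjusted p was 0.0692 to 0.882. Of the genes listed under an older symbol, kirre (listed as duf) had 9 summits, hry (h) 6, ovo (svb) 4, peb (hnt) 2 and nanos (nos) 1. With them, chosen after seeing the data, the counts were 10 of 18 for muscle and mesoderm, 3 of 14 for gap and pair-rule, 3 of 14 for cuticle, 8 of 10 for gut and 2 of 10 for germline genes, and no list changed its side of the threshold.

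**Figure D3:**
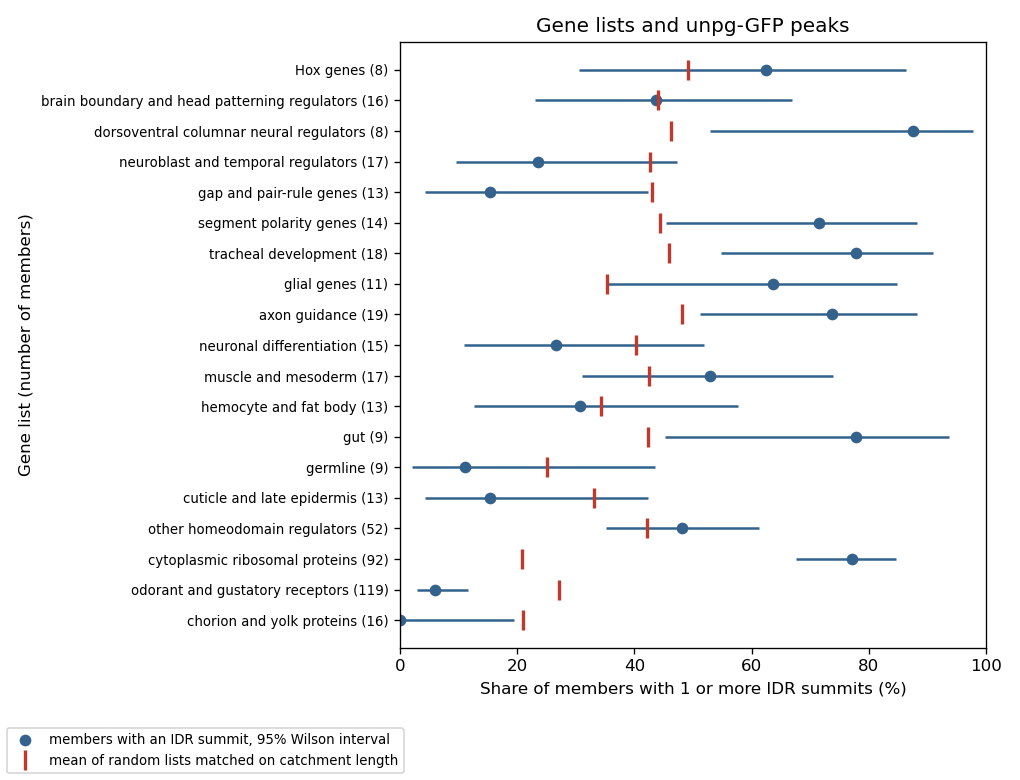
Share of members with 1 or more IDR summits (horizontal axis, percent; points with 95% Wilson intervals) for each gene list (vertical axis, number of members in parentheses), with the mean of matched random lists as red bars. Cytoplasmic ribosomal protein genes lie at 77.2% against 20.8%, and odorant and gustatory receptor genes at 5.88% against 27.2%.

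Motifs asked whether summits held the words bound by homeodomain proteins. TAATTA, a palindromic homeodomain word, was in 11.4% of summit windows and 5.62% of flank windows (ratio 2.02, adjusted exact McNemar p = 2.32e-34; 1.92 ± 0.0375 in the replicates, SD, n = 3). Its ratio was below the median ratio of 13 other words made of the same bases (0.774 of that median, with 12 of the 13 higher). Some of these words, such as ATATTA (ratio 3.09) and ATTAAT (2.12), contain ATTA as TAATTA does, so they are not an unrelated control. CAATTA was in 11.2% against 8.86% (ratio 1.26, adjusted exact McNemar p = 1.06e-05) and likewise at 0.614 of the median of its same-base words. With matched GC, added after seeing the data, CAATTA was less frequent at IDR summits than at random positions (ratio 0.848) and than at pooled summits outside the IDR set (0.897, adjusted permutation p = 0.00533 for each). TAATTA was less frequent than at random positions (0.921, adjusted permutation p = 0.00533) and did not differ detectably from outside summits (0.989, adjusted permutation p = 0.743). TTTATG, the word of the Abd-B and Caudal class, had a ratio of 1.33 (adjusted exact McNemar p = 3.02e-10) and 0.785 of its median. Among 2064 6-mers TAATTA ranked 109 (117 ± 25.7 in the replicates, SD, n = 3) and CAATTA 465; the highest were AATATT, ATATTA and TAGTAA.

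Core promoter words were also more frequent at summits. Position alone can give this, since 36.7% of IDR summits lay in promoters and the flank window lies 300 bp away. Promoters without a peak were not compared. TATCGATA, the DNA replication-related element, was in 0.920% of summit against 0.279% of flank windows (ratio 3.30, adjusted exact McNemar p = 1.33e-06), and GGTCACACT, known as Motif 1, in 0.697% against 0.195% (ratio 3.57, adjusted exact McNemar p = 1.10e-05). GGTCACACT no longer passed among the 3588 strongest peaks (ratio 1.10) or without any 1 replicate (ratios 1.93 to 2.08). AGATAAG, the GATA word, had a ratio of 1.51 (adjusted exact McNemar p = 0.0050), lost among the 3588 strongest peaks (1.33) and without any 1 replicate (1.30 to 1.38). For both words, the settings without 1 replicate hold fewer and mostly stronger peaks, so the losses cannot be tied to 1 replicate. CACACAC (ratio 0.309), GAGAGAG, the GAGA factor word (0.348), CAGGTG (0.417) and CAGCTG (0.575) were less frequent at summits than in flanks (adjusted exact McNemar p from 1.09e-37 to 8.14e-10). Summit windows were also lower in GC content than flanks, at 31.8% against 43.9%. Relative to the median of same-base words, the ratios were 0.663 (CACACAC), 0.918 (GAGAGAG), 0.845 (CAGGTG) and, turned, 1.16 (CAGCTG), none past the threshold. The GAGAGAG ratio varied between replicates (0.222, 0.461 and 0.590 in replicates 3, 4 and 5). It was 0.215 without replicate 5, 0.137 among the 3588 strongest peaks, where CACACAC stood at 0.193, and 0.523 within 100 bp of the summit. GGATTA, ATGCAAAT, CAGGTAG and CCGGAAG did not pass (adjusted exact McNemar p from 0.0634 to 1). CAGGTAG, the Zelda word, was less frequent at summits within 100 bp of the summit (ratio 0.654, adjusted exact McNemar p = 0.0250), against the left flank (0.50, 0.00665) and without replicate 3 (0.526, 0.0385), and GGATTA was more frequent against the left flank (1.25, adjusted exact McNemar p = 0.0305). Ranked among words of the same bases, CCGGAAG was above all 209 (ratio 2.78 to their median, exact p = 0.00952, adjusted p = 0.133) and CAATTA below all 59 (exact p = 0.0333, adjusted p = 0.156), each the smallest p that its number of words can give. For 11 of the 14 motifs that smallest p is too large to pass alone after adjustment, so the ranks are given as descriptions.

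**Figure D4:**
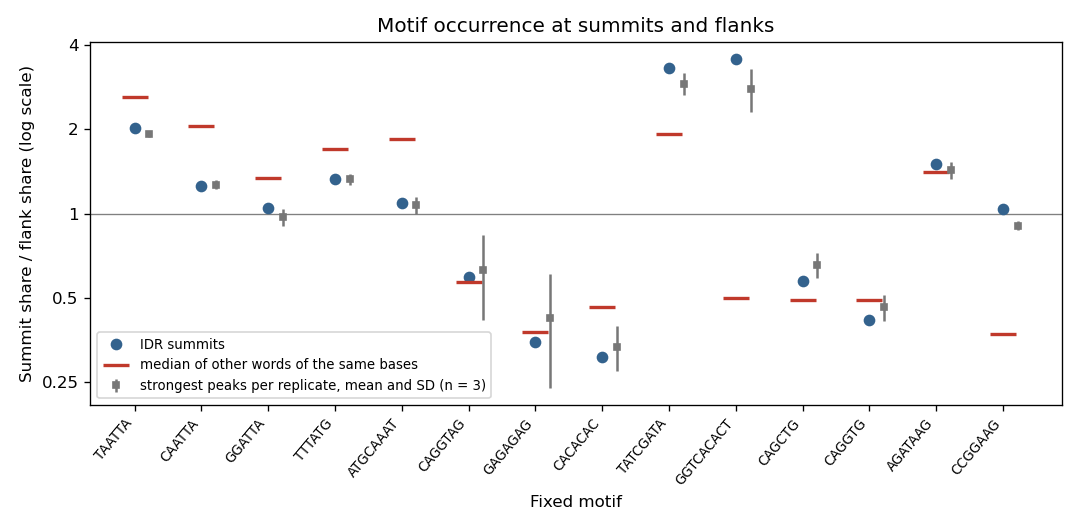
Ratio of the share of summit windows to the share of flank windows with each motif (vertical axis, log scale) for the 14 motifs (horizontal axis), over IDR summits, over the strongest peaks per replicate (mean, error bars SD, n = 3), and as the median of other words of the same bases. TAATTA lies at 2.02, below its same-base median of 2.61.

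Summits were AT-rich over a short stretch. GC content averaged 31.8% in IDR summit windows (32.4% ± 0.493 in the replicates, SD, n = 3) and 43.9% in the flanks, against 42.2% over the 6 arms. It was 39.4% at summits of pooled peaks outside the IDR set. The 718 strongest IDR peaks averaged 28.2% and the 717 weakest 34.97%.

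**Figure D5:**
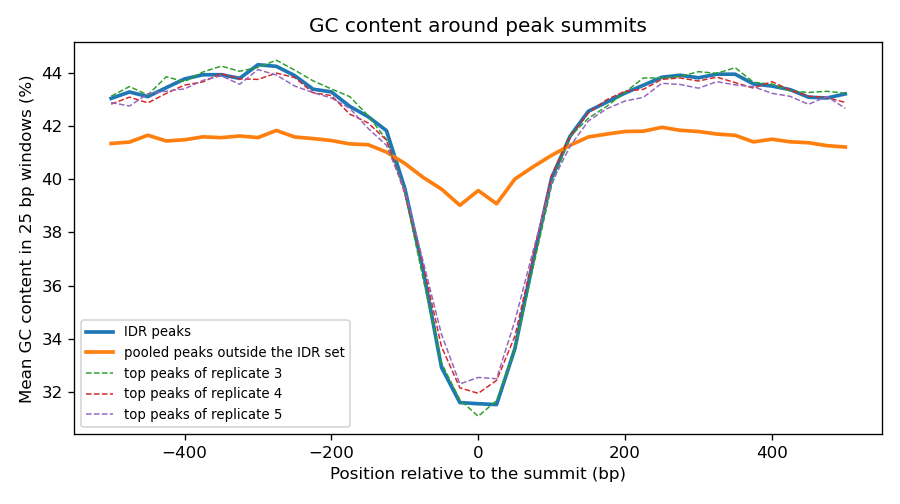
Mean GC content in 25 bp windows (vertical axis, percent) by position relative to the summit (horizontal axis, bp) for IDR peaks, pooled peaks outside the IDR set and the strongest peaks of each replicate. IDR peaks fall to 31.6% at the summit, against 39.6% for peaks outside the set.

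Strong and weak IDR peaks differed in where they lay. Promoters held 45.3% of the 1794 strongest peaks against 32.6% of the 1794 weakest (difference 12.7 percentage points, adjusted Fisher's exact p = 2.74e-14; 10.8 ± 3.33 in the replicates, SD, n = 3), and the difference was 21.5 percentage points between the 717 peaks at either end. TAATTA was in 13.9% against 9.53% (difference 4.35 percentage points, adjusted Fisher's exact p = 9.19e-05; 4.31 ± 0.354 in the replicates, SD, n = 3), a call lost between the 717 peaks at either end (2.79 percentage points, adjusted Fisher's exact p = 0.178). Summit GC content also differed with peak strength, at 28.2% in the 718 strongest and 34.97% in the 717 weakest IDR peaks. The strong and weak peaks were not matched on GC content, so their difference in TAATTA cannot be separated from base composition. TAATTA did not differ detectably between promoter summits (10.8%) and all others (11.7%; adjusted Fisher's exact p = 0.298).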

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

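Of 404 alternative values for 56 results, 295 counted as unchanged. For tested results this means the same direction and side of the threshold. Overlap shares, correlations, counts of lists and ranks have no threshold, and there it means a small change. The causes of the other changes were not tested except where stated. In tests on IDR peaks, the settings without 1 replicate keep fewer and mostly stronger peaks. Matching on GC content, leaving out promoter summits and resolving older gene symbols were added after the data had been seen. The depth of the replicates is unknown and no limit from it can be given. No paired analysis was possible because the study has 1 group.

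The overlap of replicates (79.6%) was 65.1% with 50% reciprocal overlap, 76.1% with summits within 100 bp, 84.5% for the 3588 strongest peaks, 70.5% for all peaks (13.4% at random) and 78.3 to 80.4% without each replicate. The share of IDR peaks in all 3 replicates (70.4%) was 48.7% with reciprocal overlap, 67.1% with summits within 100 bp, 98.6% for the 3588 strongest, and 75.98 to 77.97% without each replicate, where only 2 lists are needed. The mean rho (0.839) was 0.865 for the 3588 strongest.

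Intron ratios (1.06) were 0.967 with promoters of 1000 bp, 1.01 for the 3588 strongest, 0.842 against peaks outside the IDR set and 0.954 with matched GC. The 5' UTR ratio (0.841) was 0.390, 0.489, 0.621 and 1.13 in that order, past the threshold in the first 3, and other genes passed at 0.746 against outside peaks. Against outside peaks the arm ratios were 0.999 (2R), 0.90 (3L, now past the threshold), 1.05 (3R), 0.998 (4) and 1.01 (X); for the 3588 strongest they were 0.980 (3L) and 0.981 (3R). Without each replicate 3R lay at 0.954 to 0.963, X at 1.06 to 1.09 and arm 4 at 0.195 to 0.325.

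Lists above chance (1) numbered 3 with gene bodies and 2 kb, 9 without matching on catchment length, and 2 to 2 without each replicate; lists below chance (1) numbered 2 with gene bodies and 2 without matching, the second being chorion and yolk proteins in both. Without promoter summits the ribosomal protein ratio was 0.546, and the 1 list above chance was tracheal development (1.96). Among lists that did not pass, ratios that changed side were, within 1 kb of a TSS, 0.447 (Hox), 0.536 (segment polarity), 1.27 (germline) and 0.574 (other homeodomain); with gene bodies, 1.04 (brain boundary), 1.12 (neuronal differentiation), 1.16 (hemocyte) and 1.11 (germline); for the 3588 strongest, 1.07 (brain boundary) and 0.816 (other homeodomain); without matching, 1.63 (brain boundary) and 1.14 (hemocyte); without promoter summits, 1.01 (brain boundary) and 1.27 (hemocyte); and without each replicate, 0.989 to 1.14 (brain boundary) and 0.992 to 1.11 (other homeodomain).

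Relative to words of the same bases, ratios were 0.774 (TAATTA), 0.614 (CAATTA), 0.780 (GGATTA), 0.785 (TTTATG), 0.591 (ATGCAAAT), 1.05 (CAGGTAG), 0.918 (GAGAGAG), 0.663 (CACACAC), 1.71 (TATCGATA), 7.14 (GGTCACACT), 1.16 (CAGCTG), 0.845 (CAGGTG), 1.07 (AGATAAG) and 2.78 (CCGGAAG, above all 209 of its words), none past the threshold. That says little: with 13 to 34 words the rank of TAATTA, TTTATG, GAGAGAG and CACACAC cannot give p under 0.05, and 11 of the 14 motifs could not pass alone after adjustment. Ratios of summit to flank were, within 100 bp of the summit, 0.986 (GGATTA), 0.959 (ATGCAAAT), 0.654 (CAGGTAG, past the threshold) and 0.710 (CCGGAAG), and with the left flank 1.25 (GGATTA), 0.958 (ATGCAAAT) and 0.50 (CAGGTAG), the first and last past the threshold. For the 3588 strongest peaks the ratios of summit to flank were 1.10 (GGTCACACT) and 1.33 (AGATAAG), and without each replicate 1.93 to 2.08 (GGTCACACT), 1.30 to 1.38 (AGATAAG) and 0.526 to 0.583 (CAGGTAG, past the threshold without replicate 3). With matched GC, TAATTA stood at 0.921 against random positions and 0.989 against outside summits, and CAATTA at 0.848 and 0.897, all but 0.989 past the threshold in the other direction. TAATTA (rank 109) ranked 165 and CAATTA (465) 600 within 100 bp of the summit, and CAATTA 345 for the 3588 strongest. The difference in TAATTA between the strongest and weakest peaks (4.35 percentage points) was 2.79 between the 717 at either end, where fewer peaks were tested.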

Other observations

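Apart from the comparison of TAATTA with words of the same bases, the tests in this part were chosen after the data had been seen, and the value of the TAATTA comparison with summits outside the IDR set was known when it was made the test of base composition. Although the peak at mRpL41 ranked 2, mitochondrial ribosomal protein genes as a group were not occupied above matched genes (14 of 73, 19.2% against 16.4% in matched random lists, ratio 1.17, permutation p = 0.610). Of 290 tRNA genes, 29 lay within 500 bp of an IDR summit, against 16.2 ± 4.88 (SD) in random placements (permutation p = 0.020). However, tRNA genes lie in clusters and are not independent. IDR summits were also frequent in promoters and rare in coding sequence, so an excess over random placements need not be particular to tRNA genes. Promoter summits held TATCGATA in 2.31% against 0.110% of other summits (adjusted Fisher's exact p = 2.62e-20) and GGTCACACT in 1.59% against 0.176% (adjusted Fisher's exact p = 4.94e-11). CAGCTG (3.91% against 2.05%, adjusted Fisher's exact p = 2.59e-05) and CCGGAAG (0.645% against 0.242%, 0.0292) were also more frequent at promoters. TTTATG was less frequent there (12.9% against 15.5%, adjusted Fisher's exact p = 0.00697). The other 9 of the 14 motifs did not pass.

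The excess of TAATTA at summits over flanks was weighed first. Direct recognition of this word as the source of the whole excess is argued against by random positions of the same GC content, where TAATTA was more frequent than at IDR summits (ratio 0.921, permutation p = 0.0040). Base composition may account for the excess, since random positions of the same GC content held no less TAATTA. The ratio to pooled summits of matched GC outside the IDR set was 0.989 (permutation p = 0.743). That ratio cannot separate composition from binding, because the outside summits are weaker calls of the same precipitation. Only 4297 of the 22103 outside peaks were at the ceiling of the -log10 q-value, so others may not be bound regions. TAATTA stood at 0.774 of the median of other words of the same bases, but with 13 such words no rank could give p under 0.05. Some of those words also contain ATTA, so they are not an unrelated control. Binding to other words, or to this word at a minority of peaks, stays open.

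The excess of summits in promoters and their scarcity in coding sequence were weighed against GC content alone. At random positions of the same GC content, CDS was still far more frequent than at IDR summits (ratio 0.0377) and promoters less frequent (ratio 3.19), each with adjusted permutation p = 0.0028, so low GC content was not the whole cause of either. Accessible chromatin and recovery of open promoters without the tagged protein were not tested, since neither accessibility data nor an anti-GFP precipitation from untagged embryos was used here.

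The occupancy of cytoplasmic ribosomal protein genes was set against signal at promoters. With promoter summits left out the ratio was 0.546, with 5 of the list's 77 summits and 4 occupied genes left against a mean of 7.32 in matched lists. The excess over matched genes therefore lay in promoter summits. As 93.5% of the list's summits were in promoters, this outcome was largely set in advance, and it does not tell why these promoters carried summits. Whether promoter signal depends on the tagged protein was not tested, and no biological explanation of the occupancy of this list was tested.

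A further hypothesis was that the strongest promoter peaks lie at divergent gene pairs, with TSSs on opposite strands within 1 kb. Of promoter summits among the 1794 strongest IDR peaks 48.6% were at such pairs, against 35.9% among the 1794 weakest (difference 12.7 percentage points, Fisher's exact p = 2.44e-06). Of all promoter summits 44.9% were at such pairs, and 36.2% of all protein-coding genes belonged to one. These shares count summits and genes, so the share of genes is not the level expected for summits by chance. The share of promoter summits at such pairs was higher among the strongest peaks than among the weakest. Why it was higher was not tested.

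Of the 22103 pooled peaks outside the IDR set, 20 overlapped one of the 7176 strongest peaks in each of the 3 replicates (pooled rank 8046 or lower, median 10539), and 60% of these had promoter summits. In the other direction, 48 IDR peaks had no such peak in any replicate.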
